A study of Mus musculus with 12 samples.

How the data were processed

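Genomic DNA of 12 medulloblastomas, tumours of the cerebellum, was compared by 2-colour array comparative genomic hybridisation with ear DNA of the same mouse. Per the labels, every mouse carried 1 working copy of Ptch1, which encodes the receptor that holds the hedgehog pathway in check, on a C3B6F1 background. The labels put 3 tumours in a nonirradiated group, 6 in a group given 0.2 Gy of X-rays on postnatal day 1 and 3 in a group given 1.5 Gy on that day. Each array was 1 tumour, so a tumour was the replicate. Per the labels the tumour DNA carried Cy5 and the ear DNA Cy3 on every array. Without swapped dyes, a dye effect of a probe that is shared by all arrays stays in the values, but it cancels in differences between groups.

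The deposited scanner files were written by Agilent Feature Extraction 9.5.1.1 per the file headers (9.5.1 in the submitters' processing notes). The deposited log ratio is a log10 ratio of red over green processed signal. The processed signals, the median signals and the local backgrounds in the deposited files are in intensity units. The processed signals were already background-subtracted, spatially detrended and dye-normalized with a linear factor per the file headers. Flags in other columns of the deposited files mark spots as outliers, as saturated or as well above background. The deposited series table held values on the log2 scale. Set against the log10 ratios of the scanner files, each of its columns had a correlation of 1 and a slope of 3.32, so its scale and direction were settled, and its column medians ran from -0.02 to 0.01. Per the file headers the probes are placed on mouse build mm9, and all coordinates are given in that build.

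Each array's log10 ratio was turned into a log2 ratio of tumour over ear DNA and centred on the median of the autosomal probes, with no loess or quantile step. Control spots and spots with an outlier flag were left out, spots of 1 probe were averaged, and 42427 probes on the autosomes and X and 191 on Y remained. The median step between neighbouring probes was 61.6 kb. Median raw signal per array ran from 831 to 1031 in the ear channel and from 1264 to 1516 in the tumour channel, against median local backgrounds of 44.5 to 50. The noise SD of neighbouring probes was 0.10 to 0.13 on the log2 scale. The number of arrays limits the precision.

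Chromosomes were divided into segments by penalised least squares (optimal partitioning, own code; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6), after values were limited to 6 noise SDs around a running median of 7 probes. The penalty multiple of 6 was the smallest of those tried that gave 0 altered segments on 12 simulated arrays without change. Those arrays drew residuals of the real arrays at random positions. They therefore do not cover false segments from effects shared by neighbouring probes, as in dense tiles. Tested on simulated data, a shift of -0.8 was found in 99.2% of segments of 5 probes, one of -0.4 in 14.2% of them and in 92.5% of segments of 10 probes. A gain of 0.3 was found in 0% of segments of 5 probes, 27.5% of segments of 10 and 99.2% of segments of 30, so short gains of that size are mostly missed. A segment counted as altered at a mean of 0.2 or more in size over at least 5 probes. A whole-chromosome change was a chromosome median of that size. The Ptch1 window held the probes in the densely tiled Ptch1 interval and 500 kb on each side. After the data were seen, altered segments of 1 direction at most 10 probes apart were joined. A tumour then counted as having lost Ptch1 when lost segments covered at least 90% of the tile. Both rules have their alternatives among the settings below.

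The files pair no probe with a gene. The array holds 198 dense tiles (at least 20 probes at steps of up to 5 kb), of which 157 are under 10 kb. A longer tile was given the name of a gene of the lists when its length exceeded the gene's by at most 22 kb and at least 70% of the short tiles within 20 Mb lay at the spacing, within 20 kb, of a microRNA of that gene's chromosome. Gene lengths, neighbours and order came from RefSeq genes of assembly GRCm38.p6, whose coordinates are not used. This named 12 tiles, among them Xrcc5, Gli2, Cdkn2a, Smo, Gli1, Trp53, Hic1, Gli3, Ptch1, Apc and Sufu. These names rest on spacing, not on a probe annotation, and the rule was set after the files were seen. The values of 1 named tile are not reported here. Of the 170 list genes, 164 had a RefSeq entry.

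Per-tumour values were compared with two-sided exact permutation tests of the difference of means, counts of tumours with two-sided Fisher's exact tests, and chromosomes and lists with Benjamini-Hochberg adjustment. Single probes were fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes, 3 group means over all 12 arrays, Benjamini-Hochberg at 0.05) on the 42402 probes measured on every array. The irradiated mean weighted the dose groups by their 6 and 3 tumours. Tested on simulated data for irradiated against nonirradiated tumours over those 42402 probes, limma found 76.5% of shifts of -0.3 and 90.0% of shifts of -0.8, with 6 and 9 false calls, and made 0 calls without a shift. The simulated noise was independent between probes and between arrays, so these counts do not cover false calls from structure that probes or tumours share. Each shift was given to every irradiated array alike. The shares found therefore do not apply to a loss that only some irradiated tumours carry, as at Ptch1. The arrays lay on 3 slides, and values within slides and with slide as a block were computed. Slide 1 held the 3 nonirradiated tumours and 0.2 Gy replicate 4, slide 2 held 4 tumours of the 0.2 Gy group, and slide 3 held 0.2 Gy replicate 3 and the 3 tumours of the 1.5 Gy group.

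Groups, tests, gene lists, the rule for named genes and the thresholds other than the joining distance, the tile coverage and the tile naming were fixed before the data were examined. The lists were hedgehog, cell cycle and growth, tumour suppressor, granule neuron, DNA repair, chromosome 13 near Ptch1, and lymphocyte receptor loci. The rule named Ptch1, then up to 30 list members in altered segments, the 10 genes nearest to Ptch1 in the shared loss, genes of segments with a mean of 1 or more in size, and the 10 genes with the largest limma difference per contrast. Without a gene column only its first parts could be applied, and only to tiles, to neighbours of Ptch1 and to whole chromosomes. The alternatives were normexp background correction (offset 50, on median signals), the series table's values, centring without chromosome 13, removal of the trend with brightness (lowess, span 0.3) and probes well above background only. For segments they were means of 0.15 and 0.3, 3 and 10 probes, and 0.5 and 2 times the penalty. For the window they were 250 and 1000 kb and the median, for chromosomes the mean, and for limma slide as a block and a trended, robust prior. Each tumour was also left out in turn. Settings chosen after seeing the data were segments not joined, only segments of 1 Mb or longer, segments inside the Ptch1 tile left out, any overlap with the tile, and the tile left out of the window.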

Results

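Array comparative genomic hybridisation measured DNA copy number in 12 medulloblastomas of mice with 1 working copy of Ptch1, each against ear DNA of the same mouse. There were 3 tumours of nonirradiated mice, 6 of mice given 0.2 Gy of X-rays on postnatal day 1 and 3 of mice given 1.5 Gy. A log2 ratio of 0 is equal copy number in tumour and ear, and negative values are losses in the tumour. All mice were female except the one with 0.2 Gy replicate 3. Noise between neighbouring probes ranged from 0.10 to 0.13 on the log2 scale, and 1 to 46 spots per array were not well above background. The comparisons ask how copy number, at Ptch1 and over the genome, differed between tumours of irradiated and nonirradiated mice and between doses.

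A deletion over Ptch1, the hedgehog receptor gene on chromosome 13, was found in 6 of the 9 irradiated tumours and in 0 of the 3 nonirradiated ones. It had to cover at least 90% of the Ptch1 tile, a rule set after the data were seen, and all 12 tumours had a shorter loss inside the tile. Over the Ptch1 tile and 500 kb on each side (386 probes, chromosome 13, tile 63595090 to 63681764), the mean log2 ratio was -0.53 ± 0.38 (SD, n = 9) in irradiated and -0.04 ± 0.04 (SD, n = 3) in nonirradiated tumours. The irradiated tumours fell into a set near 0 and a set near -0.8. Replicates 1 to 3 of the 0.2 Gy group had values of -0.02, -0.05 and -0.01, and replicates 4 to 6 had -0.79, -0.80 and -0.76. The 3 tumours of the 1.5 Gy group lay at -0.75, -0.83 and -0.74. The difference of -0.49 did not pass the two-sided exact permutation test (p = 0.109 over 220 splits, smallest reachable p = 0.00455), nor did the tumour counts in Fisher's exact test (p = 0.182). With 6 of 12 tumours deleted, 0 of 3 against 6 of 9 is the most uneven count, so Fisher's test could not go below that p. Without 0.2 Gy replicate 1, 2 or 3 the window's exact p was 0.0364, 0.0424 or 0.0303, with differences of -0.55, -0.55 and -0.56. On slide 1 the single irradiated tumour lay at -0.79 and the 3 nonirradiated ones at a mean of -0.04, and with slide as a block the difference was -1.01.

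**Figure D1:**
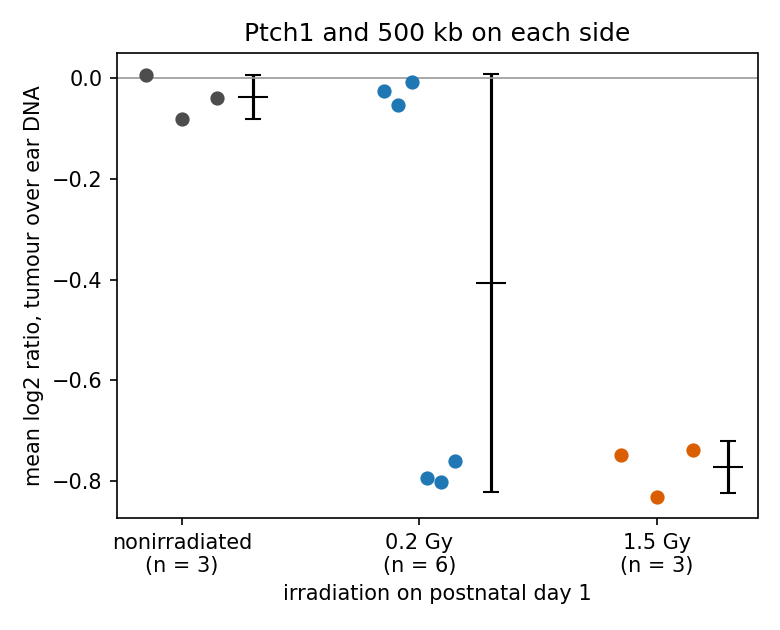
Mean log2 ratio of tumour over ear DNA in the Ptch1 window for each tumour (points), by dose group, with the group mean and SD (bars). The 3 nonirradiated tumours lie between -0.08 and 0.01, the 3 tumours of the 1.5 Gy group between -0.83 and -0.74, and the 6 tumours of the 0.2 Gy group in both ranges.

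At 0.2 Gy, 3 of 6 tumours had a deletion that covered Ptch1, against 0 of 3 nonirradiated tumours. With 3 deletions in all, these counts are the most uneven in this direction, so Fisher's test could not give a lower p for them. The Ptch1 window averaged -0.41 ± 0.42 (SD, n = 6), and this SD reflects separate sets of tumours with and without a deletion. The difference of -0.37 did not pass the two-sided exact permutation test (p = 0.286, smallest reachable p = 0.0119), nor did the counts in Fisher's exact test (p = 0.464). At 1.5 Gy, 3 of 3 tumours had such a deletion and the window averaged -0.77 ± 0.05 (SD, n = 3). All 3 values lay below those of the nonirradiated tumours, with a difference of -0.74, but 3 tumours against 3 cannot go below p = 0.1, which both exact tests gave. Between 1.5 and 0.2 Gy the window differed by -0.37 (exact permutation p = 0.310; Fisher's exact p = 0.464, 84 splits, both two-sided). For Fisher's test 3 of 3 against 3 of 6 is likewise the most uneven count in this direction, so its p could not be lower. On slide 3 the 0.2 Gy tumour lay at -0.01 and the 1.5 Gy tumours at a mean of -0.77. With slide as a block the differences were -0.76 for 0.2 Gy against nonirradiated, -1.52 for 1.5 Gy against nonirradiated and -0.77 for 1.5 against 0.2 Gy. The block values rest on 1 tumour of the 0.2 Gy group on each of slides 1 and 3.

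The 6 deletions were 30.7 to 65.4 Mb long and lay inside chromosome 13 or reached its first probe. In 0.2 Gy replicates 4 and 6 the loss ran from the first probe at 3155693 to 66887917 (63.7 Mb), with the same last lost probe, and the next retained probe lay 111 kb further. It took in the Gli3 tile, which covers a transcription factor of the hedgehog pathway, at -0.95 and -0.93. In the other 10 tumours Gli3 lay between -0.10 and -0.05. The loss of 0.2 Gy replicate 5 ran from 40728110 to 71394059 (30.7 Mb). In the 1.5 Gy group replicate 1 had lost 43525303 to 74672821 (31.1 Mb), replicate 2 22559150 to 87954868 (65.4 Mb) and replicate 3 34701248 to 80663060 (46.0 Mb). Mean log2 ratios of the 6 losses were -0.90 to -0.81, and their median ratios of tumour to ear DNA were 0.528 to 0.563.

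All 6 deletions shared 43525303 to 66887917 on chromosome 13, 23.4 Mb with 751 probes. The 10 named RefSeq neighbours nearest to Ptch1 are Fancc and Ercc6l2, genes of DNA repair, and Aopep, Hsd17b3, Slc35d2, Zfp367, Habp4, Cdc14b, Fbp1 and Fbp2. Of the 41 genes of the list fixed for this part of chromosome 13, 15 lie between the let-7 microRNA tile at 48629146 and the end of Ptch1 in the RefSeq order, so all 6 tumours had lost them. They are Ptch1, Fancc, Gas1 (a hedgehog co-receptor), Gadd45g, Syk, Nfil3, Ror2, Ntrk2, Msx2, Dok3, Fgfr4, Nsd1, Pitx1, Smad5 and Hk3. RefSeq lists 160 protein-coding genes in that part. With segments not joined, a choice made after the data were seen, the shared loss was 3.49 Mb.

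**Figure D2:**
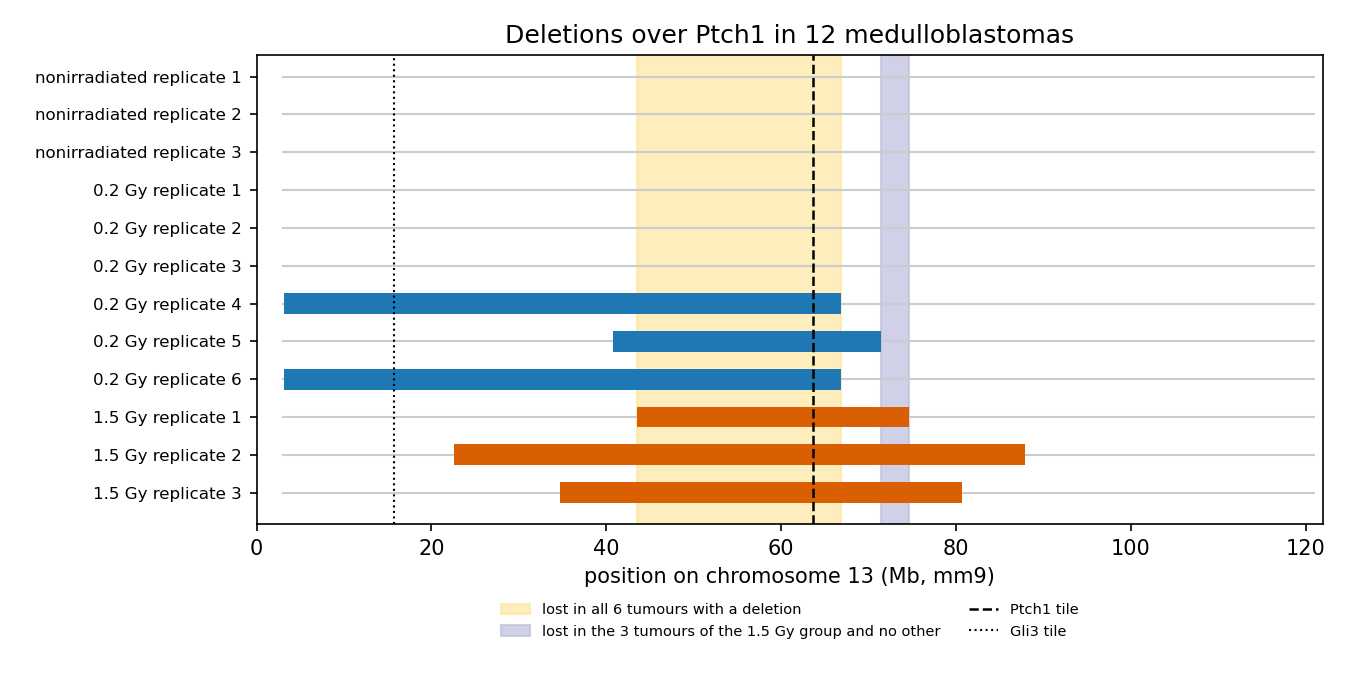
Extent of each deletion over Ptch1 along chromosome 13 (horizontal axis, Mb, build mm9) in the 12 tumours (one line each, bars coloured by dose group). Shading marks the 23.4 Mb lost in all 6 tumours with a deletion and the 3.13 Mb lost in the 3 tumours of the 1.5 Gy group alone; dashed and dotted lines mark the Ptch1 and Gli3 tiles.

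Inside Ptch1 a short stretch was far below 0 in all 12 tumours, with or without a deletion. Its 8 probes (chromosome 13, 63644455 to 63645961, 1507 bp) averaged -3.26 ± 0.27 (SD, n = 3) in the nonirradiated group, -3.03 ± 0.29 (SD, n = 6) at 0.2 Gy and -3.25 ± 0.29 (SD, n = 3) at 1.5 Gy. On the ratio scale 8.38% to 15.4% of the ear signal was left. The next 18 probes (63646094 to 63649481) lay above the rest of the tile by 0.35 ± 0.02 (SD, n = 3), 0.29 ± 0.05 (SD, n = 6) and 0.24 ± 0.01 (SD, n = 3) in the 3 groups. Within the 0.2 Gy group this went with the deletion. Replicates 1 to 3, without it, had 0.34, 0.32 and 0.32, and replicates 4 to 6, with it, had 0.26, 0.25 and 0.22. The group means are therefore not a graded change with dose. The 18 probes were raised against ear DNA, at 0.32 to 0.39, in the 3 nonirradiated tumours and in 0.2 Gy replicates 1 to 3. In the 6 tumours with a deletion over Ptch1 they lay at -0.63 to -0.53. Because of this stretch, any overlap of a lost segment with the tile counts 12 of 12 tumours and leaves a difference of 0 between groups. These probes were singled out after their values were seen.

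**Figure D3:**
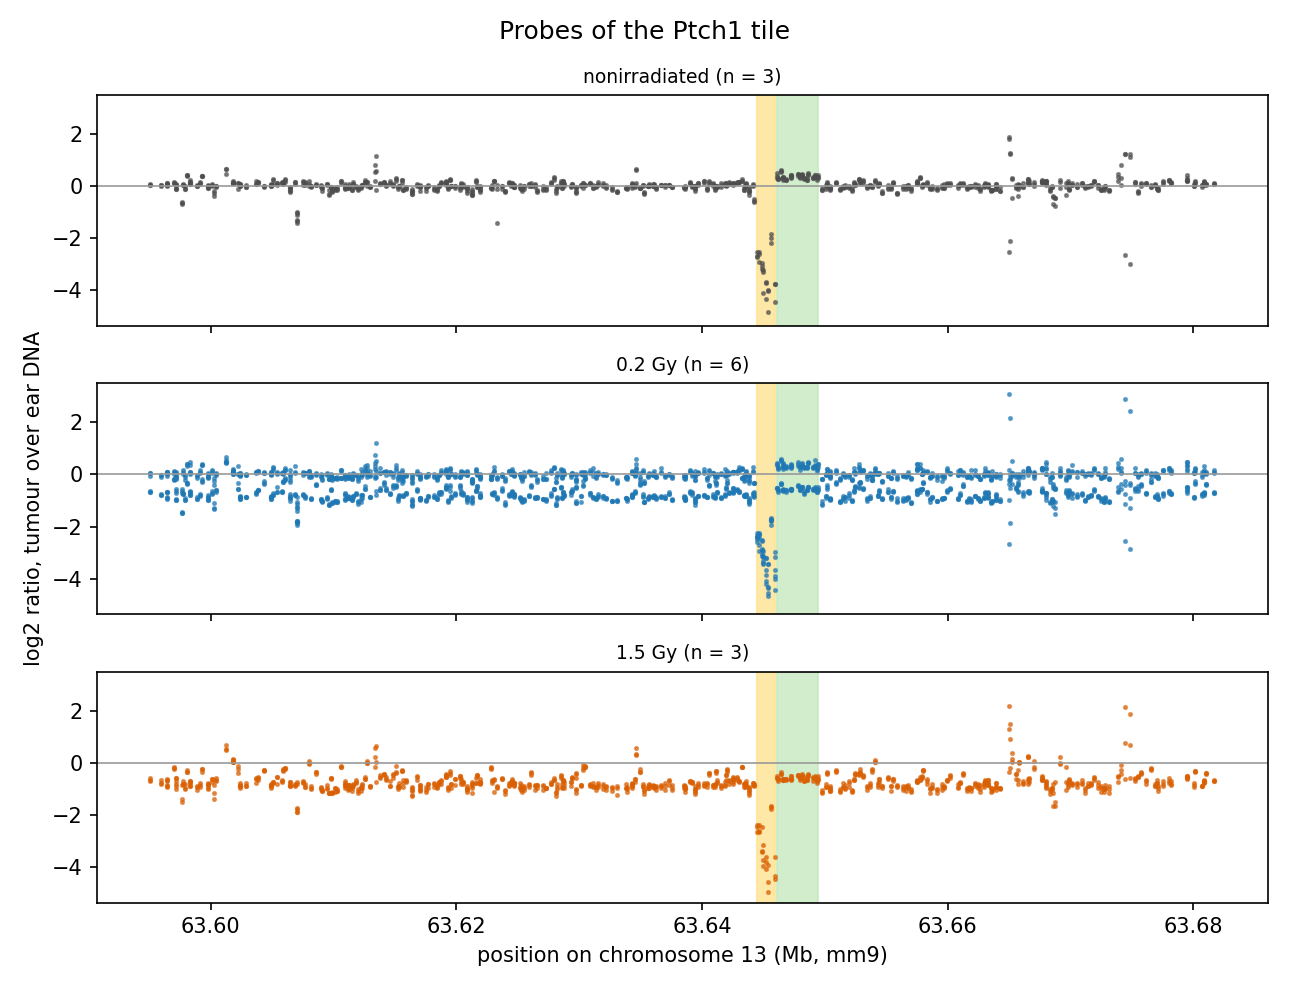
Log2 ratio of tumour over ear DNA at each of the 352 probes of the Ptch1 tile (points) against position on chromosome 13 (Mb, build mm9), with a panel per dose group. Yellow marks the 8 probes that average -3.58 to -2.70 in all 12 tumours, and green the 18 probes next to them, which lie 0.22 to 0.37 above the rest of the tile.

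Chromosome 6 was gained as a whole in 10 of 12 tumours, and its median did not separate the groups. It was 0.60 ± 0.28 (SD, n = 3) in nonirradiated and 0.41 ± 0.17 (SD, n = 9) in irradiated tumours (difference -0.19, two-sided exact permutation p = 0.195). Nonirradiated replicate 3 had the highest value, 0.91, a ratio of 1.88, and only 0.2 Gy replicate 3 (0.08) and 1.5 Gy replicate 1 (0.13) were below 0.2. Both had gained segments on part of chromosome 6, so that at most 11 tumours shared a gained probe there. As both medians lay above 0, regional gains were not told apart from a weak gain of the whole chromosome that passed the cut in parts. Outside the lymphocyte receptor list, the list genes on chromosome 6 are Smo, the hedgehog signal transducer, the growth genes Ccnd2, Met and Foxm1, and Cdkn1b, Atoh1 and Fancd2, with Atoh1 a transcription factor of granule neuron precursors. The Smo tile lay at 0.65 ± 0.27 (SD, n = 3) in nonirradiated and 0.48 ± 0.16 (SD, n = 9) in irradiated tumours. Chromosome X, which holds the list genes Ddx3x, Bcor and Dcx, had a whole-chromosome median of -0.2 or lower in 6 tumours: nonirradiated replicates 1 and 3 (-0.83, -0.98), 0.2 Gy replicates 1, 2 and 6 (-0.34, -0.91, -0.97) and 1.5 Gy replicate 1 (-0.20). A seventh, 1.5 Gy replicate 3, had lost segments on part of X, 59015600 to 68096419 (-0.22) and 103771801 to 125694603 (-0.20). Its X median was -0.14, so the same limit holds for these segments. The median of X differed by 0.31 between irradiated and nonirradiated tumours (exact permutation p = 0.341). With slide as a block the differences were -0.07 for chromosome 6 and 0.52 for X.

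Of the 20 chromosomes, 0 differed between irradiated and nonirradiated tumours after adjustment in the exact permutation test. Chromosomes 18 and 19 had unadjusted exact p of 0.0136 and 0.0182 (adjusted p = 0.182 for both) with differences of 0.01. The median of chromosome 13 was -0.30 ± 0.33 (SD, n = 9) in irradiated and -0.03 ± 0.00248 (SD, n = 3) in nonirradiated tumours, a difference of -0.27 (exact permutation p = 0.218, adjusted p = 0.343). Within slide 1 its medians were -0.80 and -0.03, and with slide as a block the difference was -0.86.

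**Figure D4:**
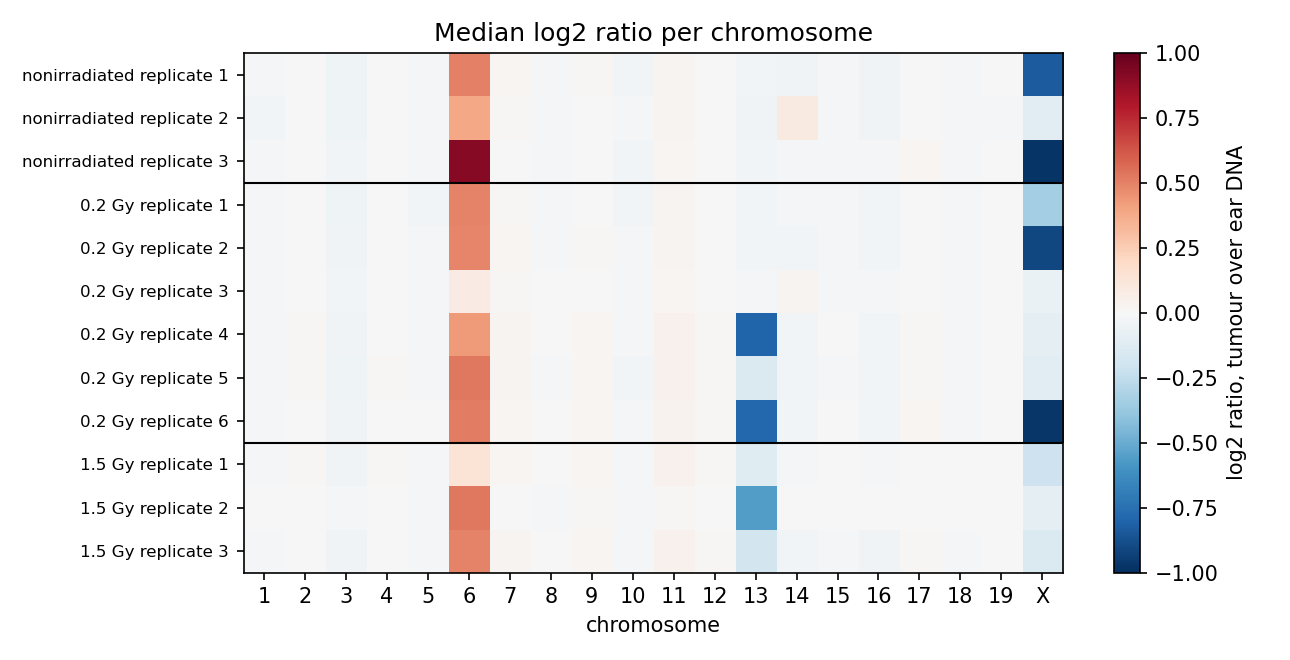
Median log2 ratio of tumour over ear DNA per chromosome (columns) and tumour (rows of the map, separated by dose group), from blue (loss) to red (gain). Chromosome 6 is at 0.2 or above in 10 tumours, X at -0.2 or below in 6, and chromosome 13 reaches -0.80 and -0.79 in 0.2 Gy replicates 4 and 6.

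The number of altered segments and the share of probes in them did not separate irradiated from nonirradiated tumours. Altered segments numbered 8.44 ± 6.15 (SD, n = 9) and 8.33 ± 4.51 (SD, n = 3) per tumour (difference 0.11, two-sided exact permutation p = 1.00), with 7 ± 4.73 (SD, n = 6) at 0.2 Gy and 11.3 ± 8.74 (SD, n = 3) at 1.5 Gy. They held 8.82% ± 3.76 (SD, n = 9) and 9.14% ± 3.16 (SD, n = 3) of probes (difference -0.325, exact permutation p = 0.864). Neither direction was stable: without nonirradiated replicate 1 or 2, 0.2 Gy replicate 3 or 1.5 Gy replicate 3 the segment difference was -0.0556, -2.06, -0.833 or -1.46. Without nonirradiated replicate 1 or 3, 0.2 Gy replicate 3 or 1.5 Gy replicate 1 the percent difference was 0.46, 0.708, 0.64 or 0.00255. On slide 1 the irradiated tumour had 3 segments and the nonirradiated ones a mean of 8.33, and with slide as a block the differences were -6.89 segments and 2.72 percent of probes. Of the 101 segments 67 were under 1 Mb, and 47 of these lay mostly in dense tiles. Segments of 1 Mb or longer were counted after the data were seen. They numbered 3.22 ± 1.79 (SD, n = 9) in irradiated and 1.67 ± 0.58 (SD, n = 3) in nonirradiated tumours. The difference was 1.56 (exact permutation p = 0.218). There were 2.5 ± 0.84 (SD, n = 6) at 0.2 Gy and 4.67 ± 2.52 (SD, n = 3) at 1.5 Gy (exact permutation p = 0.3 for 1.5 Gy against nonirradiated).

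Altered segments covered 10 regions in 3 or more tumours, 8 gained and 2 lost. The gains were chromosome 6, the 18 probes inside Ptch1 and 6 regions of 0.00114 to 0.20 Mb, and the losses were chromosome 13 around Ptch1 and chromosome X. Single tumours had other short changes: 0.2 Gy replicate 6 had lost 40917740 to 41177498 on chromosome 2 (6 probes, -1.06), and 0.2 Gy replicate 2 had gained 30616853 to 30982490 on chromosome 17 (6 probes, 0.53). The number of regions was 3 with segments of 1 Mb or longer, chosen after seeing the data, and 31 with segments of 3 probes.

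Probe by probe, most calls between the doses lay in a 3.13 Mb interval of chromosome 13 distal to Ptch1 (71475450 to 74601940, 44 probes). Its mean was -0.92 ± 0.04 (SD, n = 3) at 1.5 Gy, -0.02 ± 0.03 (SD, n = 6) at 0.2 Gy and -0.00348 ± 0.00965 (SD, n = 3) in nonirradiated tumours, and it was lost in 3 of 3 tumours at 1.5 Gy and in 0 of the other 9. The interval was set from limma's calls on the same arrays, so these values describe it and are no separate test. It is part of the deletions over Ptch1, not a further loss. It starts at the first probe retained beyond the deletion of 0.2 Gy replicate 5. Its end lies just inside that of the deletion of 1.5 Gy replicate 1, at 74672821. In limma, 45 probes were lower at 1.5 Gy than in nonirradiated tumours and 45 were lower than at 0.2 Gy. In both contrasts 44 of them lay in that interval, with median differences of -0.94 and -0.90. The other was a probe of the Gli2 tile on chromosome 1 (120732268), another hedgehog transcription factor, with differences of -0.53 and -0.60. Between irradiated and nonirradiated tumours 39 probes passed, 38 lower and all in the same interval, and 1 higher on chromosome 11 (68139227, 0.12). The 38 had a median difference of -0.32, which rests on the 1.5 Gy tumours, as the 0.2 Gy mean there was -0.02. No call lay over Ptch1, where 3 of 3 tumours at 1.5 Gy and 3 of 6 at 0.2 Gy had a deletion. That split of the 0.2 Gy group widens the spread that limma shares over the groups. The interval is therefore not the only part lost in all 1.5 Gy tumours. At 0.2 Gy against nonirradiated limma called 0 probes, with 1648 at an unadjusted p under 0.05, and 1 without nonirradiated replicate 2.

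Single tumours and the slide weighed on these counts. With slide as a block limma called 58 probes for 1.5 Gy against nonirradiated, 42 of them on chromosome 13, and 73 for 1.5 against 0.2 Gy, 44 of them on chromosome 13. It called 4 for irradiated against nonirradiated, none of them among the 39, and 0 for 0.2 Gy against nonirradiated. Without 0.2 Gy replicate 5 the counts were 103 (irradiated against nonirradiated), 114 (1.5 Gy against nonirradiated) and 115 (1.5 against 0.2 Gy), and without 1.5 Gy replicate 1 they were 75, 127 and 125. The first count was also 17 and 25 without nonirradiated replicates 1 and 2, and 21 and 13 without 1.5 Gy replicates 2 and 3. Neighbouring probes are not independent, so these counts give a place, not a number of events.

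The hedgehog genes Gli1, Gli2 and Sufu stayed near the ear level in both groups. The tiles of Gli1, Gli2 and Sufu, an inhibitor of the pathway, averaged 0.10, 0.09 and 0.10 in irradiated and 0.07, 0.08 and 0.10 in nonirradiated tumours. The 7 measured hedgehog genes of 21 averaged 0.02 ± 0.08 (SD, n = 9) in irradiated and 0.13 ± 0.05 (SD, n = 3) in nonirradiated tumours (difference -0.11, two-sided exact permutation p = 0.0591, adjusted p = 0.136; -0.27 with slide as a block). The difference came with Ptch1, Gli3 and Smo at -0.49, -0.18 and -0.17, against 0.03, 0.00 and 0.00 for Gli1, Gli2 and Sufu. Of the 12 named tiles 0 passed after adjustment, and 1, Apc, had an unadjusted exact p under 0.05 (0.00909, adjusted p = 0.109, difference 0.02).

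The tumour suppressor list had 4 measured genes of 26, Trp53, Cdkn2a, Hic1 and Apc, at 0.10 ± 0.04 (SD, n = 9) and 0.08 ± 0.05 (SD, n = 3) (exact permutation adjusted p = 0.632). Its difference of 0.01 was -0.02 without nonirradiated replicate 2 and -0.00129 with slide as a block. DNA repair had 1 measured gene of 22, Xrcc5, at 0.08 and 0.06 (exact permutation adjusted p = 0.136; 0.03 with slide as a block). After normexp correction its adjusted exact p was 0.0364 with a difference of 0.04. The list near Ptch1 had 2 measured genes, Gli3 and Ptch1, at -0.40 ± 0.32 (SD, n = 9) and -0.06 ± 0.02 (SD, n = 3) (exact permutation adjusted p = 0.230; -0.94 with slide as a block). In limma 1 gene passed when adjusted over the list alone, Ptch1 at 1.5 Gy against nonirradiated (difference -0.73, adjusted p = 0.0221 over the 2 genes near Ptch1). Over the 7 hedgehog genes, which include Ptch1, 0 passed in that contrast (smallest adjusted p = 0.0772), and 0 of 198 tiles passed when adjusted over all tiles (Ptch1 adjusted p = 0.546). The cell cycle and growth, granule neuron and lymphocyte receptor lists had 0 measured tiles. Of their 26, 21 and 18 genes, 3, 1 and 5 lie on chromosome 6.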

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

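No test in this part was chosen after its result was seen. Each of 34 measures was examined for a tumour far from the others of its group, in the 0.2 Gy group of 6 only, since groups of 3 are too small. Chance flags about 1 in 20 groups, so 1.7 such measures would arise by chance, and 5 were found. In 0.2 Gy replicate 3 the median of chromosome 6 was 0.082, with the nearest other tumour at 0.43, and its Smo tile, on the same chromosome, was at 0.19, with the nearest other at 0.50. The same tumour had the highest median of chromosome 14, 0.024. Replicate 1 had the lowest median of chromosome 18, -0.020, and replicate 4 the highest median of chromosome 19, 0.0057. No explanation of these values was tested.

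A signal also appeared at probes outside the comparisons. The 191 Y probes of 0.2 Gy replicate 3, the tumour of a male mouse per the labels, had a median tumour signal of 50.2% of the autosomal median, against at most 2.27% in the nonirradiated tumours of female mice. Its ear DNA had 54.0%, and the median log2 ratio of its Y probes was -0.08.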

How the results depend on the processing

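Segments not joined, segments of 1 Mb or longer, segments inside the Ptch1 tile left out, any overlap with the Ptch1 tile and the tile left out of the window were settings chosen after the data were seen, and the cause of the changes below was not tested. The Ptch1 window kept its direction in all 9 other settings for each of the 4 comparisons, and its side of the threshold in the 3 that could pass it, 1.5 Gy against nonirradiated being unable to (-0.55 to -0.49 for irradiated minus nonirradiated, with exact p from 0.0545 to 0.114). With tumours left out that difference ranged from -0.56 to -0.45, and 3 of 12 omissions passed. Any overlap with the tile set the difference in tumours with a loss to 0 in all 4 comparisons. The segment difference of 0.11 changed sign with normexp (-2.11), the series table (-0.667), the brightness trend removed (-0.778), probes well above background (-0.556), 3 probes (-6.56) and 2 times the penalty (-0.333), was 0 with a mean of 0.3 and up to 3.44 with segments not joined, and ranged from -2.06 to 2.44 with tumours left out. The percent difference of -0.325 changed sign with normexp (0.15) and a mean of 0.15 (0.654), was -0.905 with a mean of 0.3, and ranged from -2.14 to 0.708 with tumours left out. Of the single omissions, those named in the report changed these signs (segments -0.0556, -2.06, -0.833, -1.46; percent 0.46, 0.708, 0.64, 0.00255). The 10 recurrent regions became 18 with normexp, 27 and 6 with means of 0.15 and 0.3, 31 with 3 probes, 23 with 0.5 times the penalty and 3 with segments of 1 Mb or longer. The shared loss was 3.49 Mb with segments not joined. With normexp 1 gene list passed. The tumour suppressor difference was -0.018 without nonirradiated replicate 2 and ranged up to 0.032 with other tumours left out. In limma, irradiated against nonirradiated gave 25 probes with normexp, 23 with a trended, robust prior, 4 with slide as a block, and 13 to 103 with tumours left out. With tumours left out, 0.2 Gy against nonirradiated gave 0 to 1, 1.5 Gy against nonirradiated 44 to 127 and 1.5 against 0.2 Gy 44 to 125, the last 73 with slide as a block. The counts of chromosomes that differ, of chromosome 6 gains and of X losses stayed within 1.5 times in all settings. The GC correction was not run, since no genome of the build was given. At most 46 spots per array were not well above background, so dim signal limits few probes.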

Other observations

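The tests on the mean of the 8 Ptch1 probes, probe runs, ear signal, shared probe effects and slides in this part were chosen after the results were seen, and the correlation across autosomes and the splits of the tumours were planned. Chromosome 15 of 0.2 Gy replicate 3 had single probes far from their segment mean. Its residual SD was 0.25, against 0.12 to 0.16 in the other 11 tumours, and in the first 6 Mb of the chromosome it was 0.67. The median of that chromosome was -0.02. Of the 101 altered segments, 67 were under 1 Mb, 58 of them gains, and 47 lay mostly in dense tiles. On chromosome 11 (87568123 to 87570990) segments within 1 short region had opposite signs, 1.1 in 0.2 Gy replicate 3 and -0.60 in replicate 4. The Gli2 probe that limma called lay at -0.63, -0.74 and -0.61 in the 1.5 Gy tumours and at -0.13 in 0.2 Gy replicate 3, on the same slide.

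The stretch of 8 probes inside Ptch1 lay far below 0 in all 12 tumours. A candidate explanation is that the tumour cells had lost the working copy of Ptch1 and kept a copy that lacks this stretch. The highest mean of the 12 tumours was -2.70. The probes were picked for lying below -1 in every tumour, so a mean below -1 was fixed in advance and is no support. The pick did not set how far below -1 they lay, and -2.70 is further down than the loss of only 1 copy of a pair gives. The explanation stays open, as the structure of the kept copy is not known here. In ear DNA their median signal was 41.9% to 44.0% of that of the rest of the tile. In tumour DNA it was 3.56% to 9.77%. These shares compare different probes, which can differ in brightness, so they do not give copy numbers by themselves. For sequence variants under single probes, runs elsewhere were examined: the longest other run of autosomal probes below -1 in every tumour had 1 probe. Each tumour was set against ear DNA of its own mouse, so a variant shifts a ratio only where the tumour lost an allele. No other autosomal region was called lost in 3 or more tumours, so this comparison cannot decide about variants. A dim ear signal is argued against, since 100% of the ear spots of these probes were well above background. The structure of the engineered allele is not given in the sources used here, and DNA of other cells in the tumour sample stays open as the source of the 8.38% to 15.4% that was left.

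Tumours without a deletion may have lost the working copy by exchange of 1 parental chromosome 13 for the other, which leaves the copy number at 2. C3B6F1 mice carry chromosomes of both parental strains, so probes that match 1 strain better would then shift together. Among the nonirradiated tumours the mean pairwise correlation of probe residuals was 0.844 on chromosome 13 and at most 0.820 on the other autosomes (chromosome 18). The planned rule asked only that the mean on chromosome 13 be higher than on every other autosome, and this was met. The margin was small, and the lowest pair on chromosome 13, 0.807, lay below 0.820. That condition on the lowest pair was not part of the plan, and because of it the explanation is left open here. Beyond the last deletion (from 87954868, 410 probes), residuals of the nonirradiated tumours correlated at 0.762 to 0.921 with the profile of the others of that group, 0.2 Gy replicates 1 to 3 at 0.852, 0.919 and 0.923, 0.2 Gy replicates 4 to 6 at 0.482, 0.509 and 0.607, and the 1.5 Gy tumours at 0.486 to 0.594. The lowest irradiated value, 0.482, argues against probe effects shared by all arrays as the whole cause, and as it belongs to the tumour on the slide of the nonirradiated group, it argues against that slide too. The size of the residuals at these 410 probes split the tumours in the same way. Their SD was 1.21 to 1.41 times the median of the other autosomes in the nonirradiated tumours and 0.2 Gy replicates 1 to 3. In 0.2 Gy replicates 4 to 6 and the 1.5 Gy tumours it was 0.88 to 1.00 times that median. This measure was not planned and no test was run on it.

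Other splits of the tumours into groups of the same sizes were set beside limma's counts. For 1.5 against 0.2 Gy, 3 of 84 splits, the real one among them, gave 45 probes or more, and the highest other split gave 771. That share is under the planned 0.05, but it is not adjusted over the contrasts and these splits ignore the slide. Exchanges within slides allow only 4 arrangements, too few for a share under 0.05, so chance was not excluded. The split with 771 set 0.2 Gy replicates 1 to 3 apart, tumours without a deletion, and so points to a structure of the samples. For irradiated against nonirradiated, 5 of 100 splits gave 39 or more, so chance was not excluded. The highest other split gave 2122, many times the real count, and set nonirradiated replicate 3 and 0.2 Gy replicates 2 and 6 apart, 3 tumours with X at -0.91 or below. For 0.2 Gy against nonirradiated the real count was 0 (limma, 1648 at an unadjusted p under 0.05), which all 84 splits reach by construction, so they say nothing about chance. The same 3 tumours gave the highest of the other splits, 1995. For 1.5 Gy against nonirradiated the 10 splits are too few for a share under 0.05: the real split, 1 of the 10, gave 45 and the highest other gave 0.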
